A study of Mus musculus with 30 samples.

How the data were processed

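Hearts of WT and S55L mice were measured in 6 groups of 5 deposited columns, 4 groups in the postpartum study and 2 in the diet study. Per the labels' protocols, RNA was taken with the Qiagen RNeasy Mini kit, and 3' mRNA libraries were made with the Lexogen QuantSeq FWD kit. The deposited values are raw read counts per gene from HTSeq 0.6.1, after trimming with Trimmomatic 0.39 and alignment with STAR 2.7.0f to the build GRCm39.p6, per the submitters' processing notes. Those notes also name DESeq2, with a version of 3.21. They do not state the annotation release, the strand setting or the HTSeq mode, so overlapping, antisense and near-identical genes are uncertain, among them Hba-a1, Hba-a2, Rpl3, Vmn2r3 and Gsta2. The labels do not state that each library is a separate mouse, so p-values measure the spread between these libraries.

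The 2 tables hold 78258 genes for the postpartum study and 56691 for the diet study, so they were counted on different annotations and were never fitted together. Gene symbols came from GENCODE M21, a GRCm38 annotation, matched by Ensembl ID, and no coordinates were used. A symbol was found for 51487 IDs of the postpartum study, which held 99.4% of its reads on genes, and for 52073 IDs of the diet study, which held 99.8%. The HTSeq summary lines stayed out of library sizes and tests: reads aligned to several places made up 17.5% to 27.3% in the postpartum and 35.2% to 39.1% in the diet study, reads on several genes 4.45% to 7.08% and 1.97% to 2.50%, and reads on no gene 5.65% to 10.1% and 1.43% to 1.74%.

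Identical columns were found by comparing every pair of libraries. Identical columns within a group (plate rows A and B) were used once and assumed to be row A. The column deposited under both diets was left out. Fitted were 18 libraries of the postpartum and 8 of the diet study, not the planned 20 and 10. For any other pair the chi-square per gene was at least 2.39 in the postpartum and 5.54 in the diet study.

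Genes were filtered with filterByExpr by group and scaled by trimmed means (TMM), and tested with the edgeR 4.0.16 quasi-likelihood test (glmQLFit, robust) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 4 groups of the postpartum study were fitted together, and the 2 diets apart from them. The common biological coefficient of variation was 0.199 in the postpartum and 0.299 in the diet study. The standard error of a log2 fold change (SE) was the fold change divided by the square root of the F statistic. CPM come from edgeR with these scaled library sizes and are given as mean ± SD over libraries. Where 1 group had no counts, a fold was computed against 3 counts over the group, which is 0.347 CPM in WT naive and 0.334 in WT PP. With 1 to 3 counts the ratio is given with its 95% counting interval.

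Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and again with the correlation estimated for each list. Of 48 lists, 42 had at least 3 measured members in the postpartum study and 43 in the diet study, and 7 list symbols matched no gene. The genes called among a list's members were counted over all genes and again adjusted over the list alone. The diet score was the mean over the genes called between S55L PP and WT PP of the signed difference in log2 CPM, with an exact permutation test. The tests, gene lists, first set of alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 6 called genes with the largest rise and the 6 with the largest fall among genes with a mean of at least 5 CPM and a proper symbol, up to 3 called members of each described list with the lowest adjusted p, and a fixed panel of 20 genes in every comparison. Genes outside the rule, such as Cd74, H2-Eb1, H2-Ab1, Serpina3n, Mmp3 and Alas2, and Ucp3 and Lgals4 outside WT, were chosen after their values were seen. Some genes that these choices include are not reported here.

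The numbers in the titles were checked as a possible pairing: same-numbered WT PP and S55L PP libraries deviated together from their group means (r = 0.119 to 0.333 over 4 pairs), while for each other pair of groups at least 1 pair was at or below 0.1. The labels do not say what a number stands for. The alternatives of that first set were DESeq2 size factors, total counts, no filter, the DESeq2 1.42.0 test, limma voom with quality weights, removal of mitochondrially encoded genes, the plate column as a term, the number as a replicate block, only the compared groups, and leaving out each library in turn. Added after seeing the data were all deposited columns, the library under both diets kept under either, no libraries under 1200000 reads in the diet study, counts thinned to 1418715 reads, an outer plate row as a term, and no outer-row libraries.

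Tests were run on counts simulated from these libraries' means and sizes, with 200 genes changed and a list shifted. Of genes changed 2-fold, 76.1% were recovered between the naive genotypes (11672 genes in the run), 62.7% between the PP genotypes (11732), 52.2% between WT PP and WT naive (11750), 73.1% between S55L PP and S55L naive (11696) and 8.96% between the diets (10124). Of genes changed 4-fold, 100%, 98.5%, 93.9%, 100% and 86.4% were recovered, and 3.79%, 4.20%, 6.09%, 3.15% and 1.54% of the calls were false. The interaction and diet score were not simulated, nor was recovery split by level.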

Results

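Hearts of mice carrying the p.S55L point mutation of CHCHD10, a mitochondrial intermembrane space protein, and hearts of wild-type (WT) mice were profiled by 3' mRNA sequencing. In the postpartum study the animals were either naive, aged to 100 days, or postpartum (PP), bred at 65 days and killed on postpartum day 0. In the diet study all animals were S55L and postpartum, and had received either a control diet or a diet with EH301 during breeding. EH301 is a supplement that combines nicotinamide riboside, a precursor of NAD, with pterostilbene. Each of the 6 groups was deposited as 5 count columns. WT PP columns 1 and 2 held identical counts for every gene, as did S55L PP columns 1 and 2, and each of these pairs was counted as 1 library (n = 4). Control diet column 5 was identical to EH301 diet column 6, so its diet is unknown and both columns were left out (n = 4 against 4). Reads on genes per library ranged from 1418715 to 2307283 in WT naive, 1897249 to 2949993 in WT PP, 3369420 to 5131316 in S55L naive and 2755500 to 4157372 in S55L PP. They ranged from 466651 to 2982870 on the control diet and from 1141997 to 3048461 on the EH301 diet. Reads on genes made up 58.3% to 61.6% of all reads in WT libraries and 66.3% to 69.2% in S55L libraries of the postpartum study, and these ranges did not overlap. Genotype and position on the library plate, read from a well code in the column names, were nearly the same split: WT libraries lay in plate column 1, except WT PP 1 in column 2, and S55L libraries in columns 2 and 3. The first principal component of log2 CPM held 54.3% of the variance in the postpartum study and 60.2% in the diet study.

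The S55L naive against WT naive comparison asks what the mutation does in the heart before any pregnancy. The Chchd10 transcript (ENSMUSG00000049422) itself was higher in the mutant, at 4501 ± 715 CPM against 2719 ± 227 (SD, n = 5 each; log2 fold change 0.73, SE 0.19, adjusted p = 0.0028), and all 5 S55L libraries lay above all 5 WT libraries. The counts near the 3' end do not read the mutated codon, so this level does not check the genotype. The strongest evidence of change was for Mthfd2, a mitochondrial folate enzyme, which rose from 2.63 ± 1.54 to 326 ± 54.1 CPM (log2 fold change 6.97, SE 0.28, adjusted p = 1.6e-16). Gdf15, a secreted stress factor, rose from 0.781 ± 0.861 to 190.1 ± 53.0 CPM (log2 fold change 8.01, SE 0.57, adjusted p = 6.3e-09). Atf4, the transcription factor of the integrated stress response, rose from 46.1 ± 7.23 to 297 ± 27.8 CPM (log2 fold change 2.68, SE 0.19, adjusted p = 1.6e-11). Cox7a1, the heart and muscle form of a cytochrome c oxidase subunit, fell, with a log2 fold change of -2.41 (SE 0.15, adjusted p = 1.5e-12), and Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell with -2.67 (SE 0.18, adjusted p = 6.9e-12). For Mthfd2, Gdf15, Atf4, Cox7a1 and Hrc too the 5 libraries of each genotype did not overlap.

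**Figure D1:**
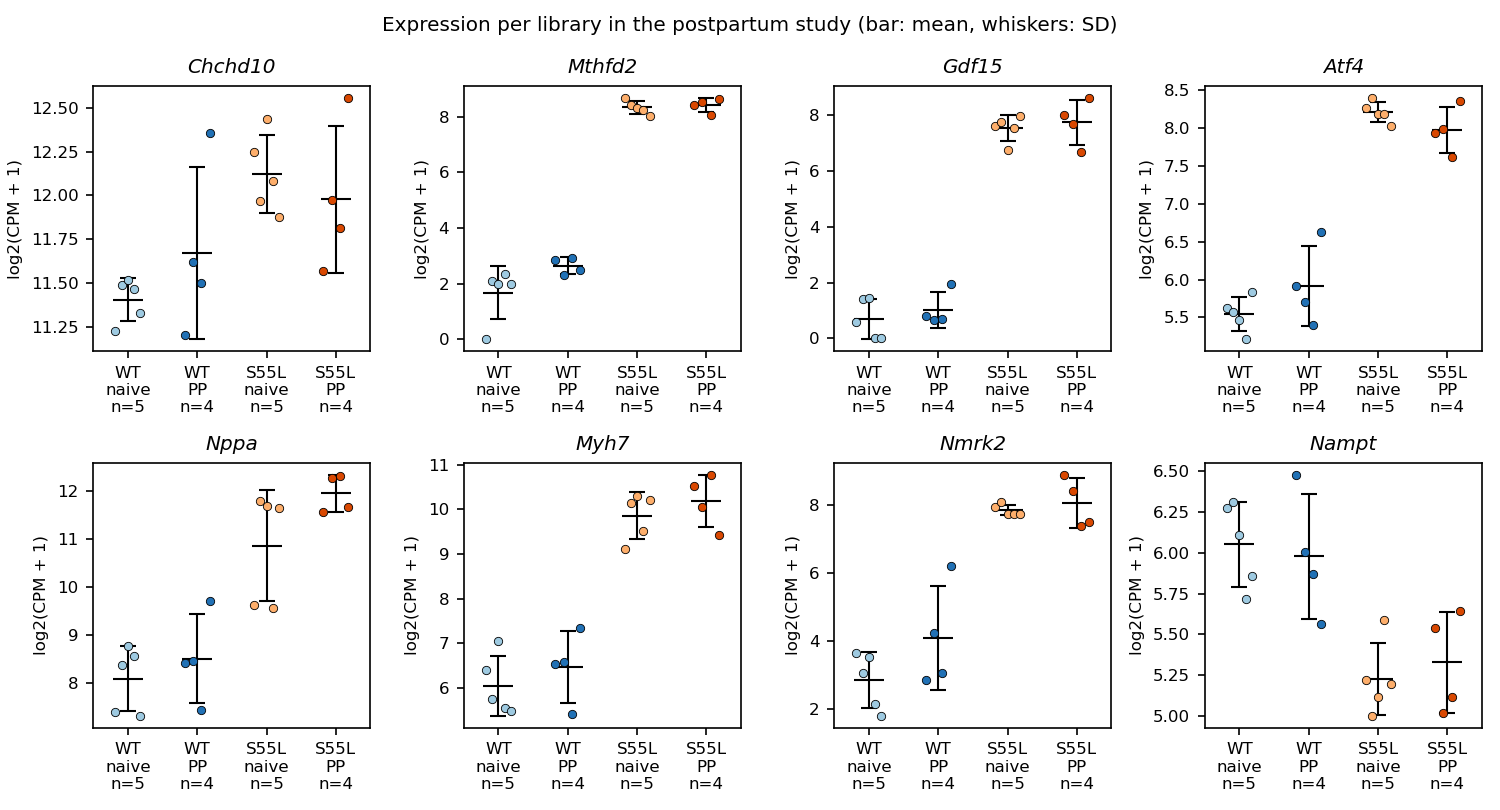
Expression of 8 genes in each library of the postpartum study, on a log2 scale of CPM plus 1, by group, with the group mean as a bar and the SD as whiskers (n = 5 naive and 4 PP libraries per genotype). All S55L libraries lie above all WT libraries for Mthfd2, Gdf15, Atf4 and Myh7, in naive and in PP mice.

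The integrated stress response, serine and one-carbon, and antioxidant lists were higher in the mutant, heat shock only with the preset correlation, and the unfolded protein response and mitochondrial chaperones did not pass. In the integrated stress response list 27 of 33 measured members rose and 1 fell (28 and 1 adjusted over the list alone). The list had a median log2 fold change of 1.73, with camera adjusted p = 3.9e-14 and adjusted p = 0.0090 with an estimated correlation, and the same median with the 2 members without WT counts at their bound. Members included Chac1, which degrades glutathione (3.80, SE 0.24 on the log2 scale), the glycyl-tRNA synthetase gene Gars (2.67, SE 0.18), Trib3, a target of ATF4 (4.53, SE 0.36), and Ddit3, which encodes CHOP (1.41, SE 0.22). Fgf21, a secreted metabolic hormone, had no counts in WT naive libraries and 6.06 ± 2.35 CPM in S55L naive libraries, at least 17.7-fold higher when 3 counts over the group are taken as the WT floor. In the list of serine, one-carbon and proline synthesis 9 of 17 measured members rose (9 adjusted over the list alone). Its median log2 fold change was 1.56, with camera adjusted p = 1.4e-06 and adjusted p = 0.0072 with an estimated correlation. Besides Mthfd2 these included Psat1 of serine synthesis (5.92, SE 0.42), Aldh18a1 of proline synthesis (3.99, SE 0.28) and Aldh1l2, a mitochondrial folate dehydrogenase (2.79, SE 0.24). Phgdh, the entry enzyme of serine synthesis, had 2 counts in all WT naive libraries together, and its CPM was 65.6-fold (95% counting interval 18.03 to 544) higher in S55L naive. In the antioxidant, glutathione and ferroptosis list 16 of 27 measured members rose and 3 fell (18 and 3 adjusted over the list alone). The list median was 0.94, with camera adjusted p = 1e-07 and adjusted p = 0.015 with an estimated correlation. Srxn1, which repairs oxidised peroxiredoxins, rose by 4.23 (SE 0.21) on the log2 scale and the glutathione transferase Gsta4 by 2.39 (SE 0.15), while Gpx4, the lipid peroxidase that blocks ferroptosis, was at -0.29 (SE 0.54, adjusted p = 0.69). The cystine transporter gene Slc7a11 had no counts in WT naive libraries and was at least 33.96-fold higher in S55L naive. In the heat shock and proteotoxic stress list 11 of 15 measured members rose (12 adjusted over the list alone). The list median was 0.88, with camera adjusted p = 2.6e-05, but adjusted p = 0.082 with an estimated correlation. Its members Sqstm1, an autophagy receptor, and Hsp90aa1 rose by 2.72 and 2.16. Mitochondrial proteases and chaperones went both ways, with 7 of 17 members up and 4 down (camera adjusted p = 0.21). Among them Lonp1, the matrix protease, rose by 1.74 (SE 0.14), Afg3l2 by 1.005 (SE 0.15) and Hspa9 by 0.90 (SE 0.13). The list of the unfolded protein response of the endoplasmic reticulum did not pass, with 5 members up and 5 down of 21 (median -0.13, camera adjusted p = 0.74). Its chaperone gene Calr fell by 1.44 on the log2 scale.

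The heart failure, extracellular matrix, fibroblast and macrophage lists were higher by camera, and of these the macrophage list alone also with an estimated correlation. In the heart failure and hypertrophy list 17 of 21 measured members rose and 2 fell (17 and 2 adjusted over the list alone). Its median log2 fold change was 2.30, with camera adjusted p = 1.3e-07, but adjusted p = 0.11 with an estimated correlation. The natriuretic peptide genes were higher, with Nppa at 2307 ± 1407 against 296 ± 126 CPM (log2 fold change 2.97, SE 0.54, adjusted p = 0.00047) and Nppb at a log2 fold change of 2.41 (SE 0.72, adjusted p = 0.014). Myh7, the beta-myosin heavy chain, rose by 3.76 (SE 0.42) and Acta1, skeletal alpha-actin, by 2.30 (SE 0.36), while Myh6, the alpha-myosin heavy chain of the adult mouse heart, fell by 0.57 (SE 0.16, adjusted p = 0.0042). With total counts as the scaling the Myh6 change was -0.32 and no longer called (adjusted p = 0.081, 1.7e-05 to 0.35 over its alternatives). Uchl1, a deubiquitinase, Ankrd1, a stretch-responsive sarcomere protein, and Enah, an actin regulator, rose by 5.33, 2.96 and 1.56. In the extracellular matrix list 26 of 38 measured members rose and 1 fell (28 and 1 adjusted over the list alone). The list median was 1.001, with camera adjusted p = 2.8e-09, but adjusted p = 0.11 with an estimated correlation. Its members Col5a2 and Col8a1 rose by 1.81 and 2.33. Of the fibroblast markers 5 of 12 measured members rose (5 adjusted over the list alone), among them Col1a1 (1.82), Col1a2 (1.20) and Mfap5 (2.03). The list had median 0.48, camera adjusted p = 0.013, and adjusted p = 0.13 with an estimated correlation. Macrophage markers were higher as a group, since 11 of 12 measured members rose (12 adjusted over the list alone). The list median was 1.88, with camera adjusted p = 1.6e-08 and adjusted p = 0.0072 with an estimated correlation. The complement gene C1qc rose by 2.30 (SE 0.17), the growth factor receptor Csf1r by 2.40 (SE 0.20) and Adgre1, which encodes F4/80, by 2.64 (SE 0.24). Endothelial markers were lower (6 of 13 fell, median -0.48, camera adjusted p = 0.0035, adjusted p = 0.11 with an estimated correlation), among them Ly6c1 (-0.98). Of the smooth muscle and pericyte markers 8 of 11 fell, such as Vtn (-1.73) and Rgs5 (-0.87), while Acta2 rose (3.45). That list had a median of -0.66, camera adjusted p = 0.022 and adjusted p = 0.18 with an estimated correlation. Atrial cardiomyocyte markers went both ways and did not pass as a list (camera adjusted p = 0.33): 4 rose and 3 fell of 7, with Dkk3 at 3.43, the potassium channel Kcnj3 at -2.69, and Bmp10 without counts in WT naive and at least 39.8-fold higher in S55L naive.

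The lists of mitochondrially encoded mRNAs and of nuclear subunits of complexes I, II and III and ATP synthase were lower by camera, and complex IV only with the preset correlation and without a plate term. Of the nuclear complex I subunits 26 of 36 measured members fell (26 adjusted over the list alone) and none rose. Its median log2 fold change was -0.64, with camera adjusted p = 4e-09 and adjusted p = 0.011 with an estimated correlation, and Ndufv1, Ndufa3 and Ndufb11 were at -1.82, -1.68 and -1.10. Of the complex II and III subunits with cytochrome c 10 of 14 measured members fell (13 adjusted over the list alone). The list median was -0.50, with camera adjusted p = 1.6e-05 and adjusted p = 0.037 with an estimated correlation. Cyc1 and Cycs were at -1.20 and -1.05. In complex IV 2 of 14 measured members rose and 7 fell (2 and 9 adjusted over the list alone), with median -0.37 and camera adjusted p = 0.015, but adjusted p = 0.12 with an estimated correlation. The heart and muscle forms Cox7a1 and Cox8b fell (-2.41 and -2.11), and the form made in most other tissues, Cox6a1, rose (1.92). Of the nuclear ATP synthase subunits 1 of 15 measured members rose and 12 fell (1 and 12 adjusted over the list alone). The list median was -0.66, with camera adjusted p = 7.4e-05 and adjusted p = 0.0072 with an estimated correlation. Atp5e, Atp5j2 and Atp5g1 were at -1.29, -0.91 and -1.32. Of the mitochondrially encoded mRNAs 11 of 12 measured members fell (12 adjusted over the list alone). The median log2 fold change of the list was -1.12, with camera adjusted p = 1.2e-07 and adjusted p = 0.047 with an estimated correlation; mt-Co3, mt-Nd3 and mt-Co2 were at -1.52, -1.40 and -1.10. Mitochondrially encoded genes took 14.4% ± 0.475 of the reads on genes in S55L naive libraries and 22.3% ± 1.85 in WT naive (SD, n = 5 each). The mitochondrial ribosome list moved less, with 5 up and 27 down of 64 (median -0.24, camera adjusted p = 0.0071, adjusted p = 0.28 with an estimated correlation), and with total counts as the scaling its median was 0.01. Among CHCHD and MICOS proteins, which shape the inner membrane, 3 rose and 5 fell of 17. Chchd4 was at 0.89, Chchd6 at 1.24, and the list did not pass (camera adjusted p = 0.29).

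Fatty acid, branched-chain amino acid, calcium handling and adult sarcomere lists were lower too, while glycolysis and NAD metabolism did not pass. In fatty acid uptake and beta-oxidation 2 of 30 measured members rose and 24 fell (2 and 25 adjusted over the list alone). Its median log2 fold change was -0.93, with camera adjusted p = 6.5e-10 and adjusted p = 0.0090 with an estimated correlation. Acsl1, which activates long-chain fatty acids, was at -1.42 (SE 0.13). The fatty acid transporter Slc27a1 and the thiolase Acaa2 were at -2.04 (SE 0.21) and -1.51 (SE 0.17). In branched-chain amino acid catabolism 1 of 19 measured members rose and 15 fell (1 and 15 adjusted over the list alone). The list median was -1.02, with camera adjusted p = 3.1e-07 and adjusted p = 0.0090 with an estimated correlation. Ivd, Ppm1k and Dbt were at -1.94, -2.23 and -1.48. The smaller tricarboxylic acid cycle (8 of 19 fell) and ketone body (4 of 6 fell) lists had camera adjusted p = 0.015 and 0.016, and adjusted p = 0.29 and 0.11 with an estimated correlation. The first lost its call with total counts as the scaling (median -0.06, adjusted p = 0.13, 0.0038 to 0.65 over its alternatives). Glycolysis and glucose uptake had 9 members up and 7 down of 25 and did not pass (camera adjusted p = 0.95). Hk1 was at 1.55 and the glycolysis regulator Pfkfb1 at -4.20 (SE 0.35), the lowest fold change of the genes named by size. NAD metabolism had 5 up and 5 down of 22 (camera adjusted p = 0.92). In it Nmrk2, the muscle nicotinamide riboside kinase, rose from 7.03 ± 4.02 to 231 ± 26.5 CPM (log2 fold change 5.04, SE 0.66, adjusted p = 2.1e-05), and Nampt, the enzyme of the salvage route from nicotinamide, fell from 66.2 ± 11.7 to 36.8 ± 6.16 CPM (-0.85, SE 0.18, adjusted p = 0.00037). In calcium handling and conduction 2 of 22 measured members rose and 14 fell (2 and 15 adjusted over the list alone). Its median log2 fold change was -0.90, with camera adjusted p = 1.8e-05 and adjusted p = 0.020 with an estimated correlation, and beside Hrc the ryanodine receptor Ryr2 was at -1.77 (SE 0.20). Among adult sarcomere genes 15 of 20 measured members fell (15 adjusted over the list alone). The list median was -0.90, with camera adjusted p = 1.1e-07 and adjusted p = 0.022 with an estimated correlation. Cmya5, Tnni3 and Myl3 were at -2.34, -1.65 and -1.79. Among circadian clock genes 1 of 17 measured members rose and 8 fell (1 and 9 adjusted over the list alone), with median -0.60, camera adjusted p = 0.0074 and adjusted p = 0.13 with an estimated correlation. The clock output genes Hlf and the repressor Nr1d1 were at -2.60 and -1.49. In the proliferation list 10 of 24 measured members rose and 2 fell (10 and 2 adjusted over the list alone), and Cdk1 was at 2.45 while Cenpf was at -3.25. That list passed by camera (median 0.85, adjusted p = 0.021) but had adjusted p = 0.44 with an estimated correlation, and without S55L naive 3, without S55L naive 5 or with total counts as the scaling it did not pass (adjusted p = 0.092, 0.062 and 0.082, 8.3e-05 to 0.48 over its alternatives).

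Of 11945 genes tested, 5192 differed between S55L naive and WT naive (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05): 2614 rose and 2578 fell, of which 1169 rose and 1114 fell at least 2-fold. In 3675 of the 5192 the 5 libraries of each genotype did not overlap, and over all genes the share without overlap was 32.2% where chance gives 0.794%. Among the largest rises, Krt18, a keratin of simple epithelia, had no counts in WT naive and was at least 81.8-fold higher in S55L naive, and Ostn, a secreted muscle peptide, was at least 40.4-fold higher. Vmn2r3, a member of a large family of vomeronasal receptor genes whose reads can be shared, had 1 count in WT naive and was 262-fold (95% counting interval 46.9 to 10360) higher. These intervals and floors cover counting error only. They leave out the spread between libraries and, as the reads carry no molecular identifiers, repeated reads of 1 molecule. The largest falls after Pfkfb1 were Sbk2 (-4.05), Lingo3 (-3.92), Tmem82 (-3.79), the secreted phospholipase Pla2g5 (-3.74) and the Z-disc gene Myot (-3.66). Of the called genes named above, only Myh6 had overlapping groups. Pdk4 (-0.34, SE 0.28, adjusted p = 0.35) and Tfrc (0.94, SE 0.42, adjusted p = 0.081) were not called. By camera 9 of 42 lists were higher and 15 lower, and 4 and 8 of these kept their call with an estimated correlation. Lists of iron handling and heme, the cytosolic ribosome, the interferon response, glucocorticoid-responsive genes, prolactin and STAT5-responsive genes, cholesterol synthesis, lipogenesis and immediate early genes did not pass (camera adjusted p = 0.11 to 0.95), nor did the erythroid markers (0 up and 3 down of 7, median -0.97, camera adjusted p = 0.052, but 0.032, 0.046 and 0.040 without WT naive 1, WT naive 4 or S55L naive 4, 0.0038 to 0.44 over its alternatives). Scaling by total counts moved the median log2 fold change of all genes by 0.24 and gave 4013 genes up and 1481 down, so directions are relative to the scaling by trimmed means. With the plate column as a term, which rests on WT PP 1 as the only WT library in a column with S55L libraries, 2873 genes were called (1386 up and 1487 down), 2497 of them among the 5192. That term kept Mthfd2, Gdf15, Atf4, Myh7, Cox7a1, Hrc and C1qc past the threshold. It raised the SE of all genes 2.02-fold at the median, and of the 2695 calls that ended, 1181 had a log2 fold change as large or larger with the term and 125 turned. In 2178 of the 2695 the SE grew by a larger factor than the fold change shrank. Nppa went from 2.97 (SE 0.54) to 3.37 (SE 1.31), Nppb from 2.41 (SE 0.72) to 3.93 (SE 1.69), Chchd6 from 1.24 (SE 0.19) to 0.97 (SE 0.42), Ly6c1 from -0.98 (SE 0.16) to -0.76 (SE 0.29), Ddit3 from 1.41 (SE 0.22) to 1.02 (SE 0.42) and Myh6 from -0.57 (SE 0.16) to -0.41 (SE 0.31), where the call ended mainly through the larger SE. The change itself shrank for Sbk2, from -4.05 (SE 0.49) to -2.39 (SE 0.89), Uqcr11, from -1.10 (SE 0.16) to -0.53 (SE 0.29), and Nr1d1, from -1.49 (SE 0.23) to -0.65 (SE 0.45). The calls of Krt18, Ostn, Bmp10, Vmn2r3, Fgf21 and Ltbp2 ended too, and as these had 0 or 1 count in WT naive their fitted change with the term is no bound and is not given. The adjusted p with the term was 0.082 for Nppa (6.6e-09 to 0.082 over its alternatives), 0.11 for Nppb (4.4e-05 to 0.11) and 0.076 for Ddit3 (8.1e-17 to 0.076). Of the lists that lost their call with the term, the median stayed at a similar size or grew for endothelial (-0.45 against -0.48), smooth muscle (-0.98 against -0.66) and proliferation genes (1.05 against 0.85). It moved toward 0 for complex IV (-0.09 against -0.37), the mitochondrial ribosome (-0.04 against -0.24), the tricarboxylic acid cycle (-0.17 against -0.31) and ketone bodies (-0.32 against -0.58).

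**Figure D2:**
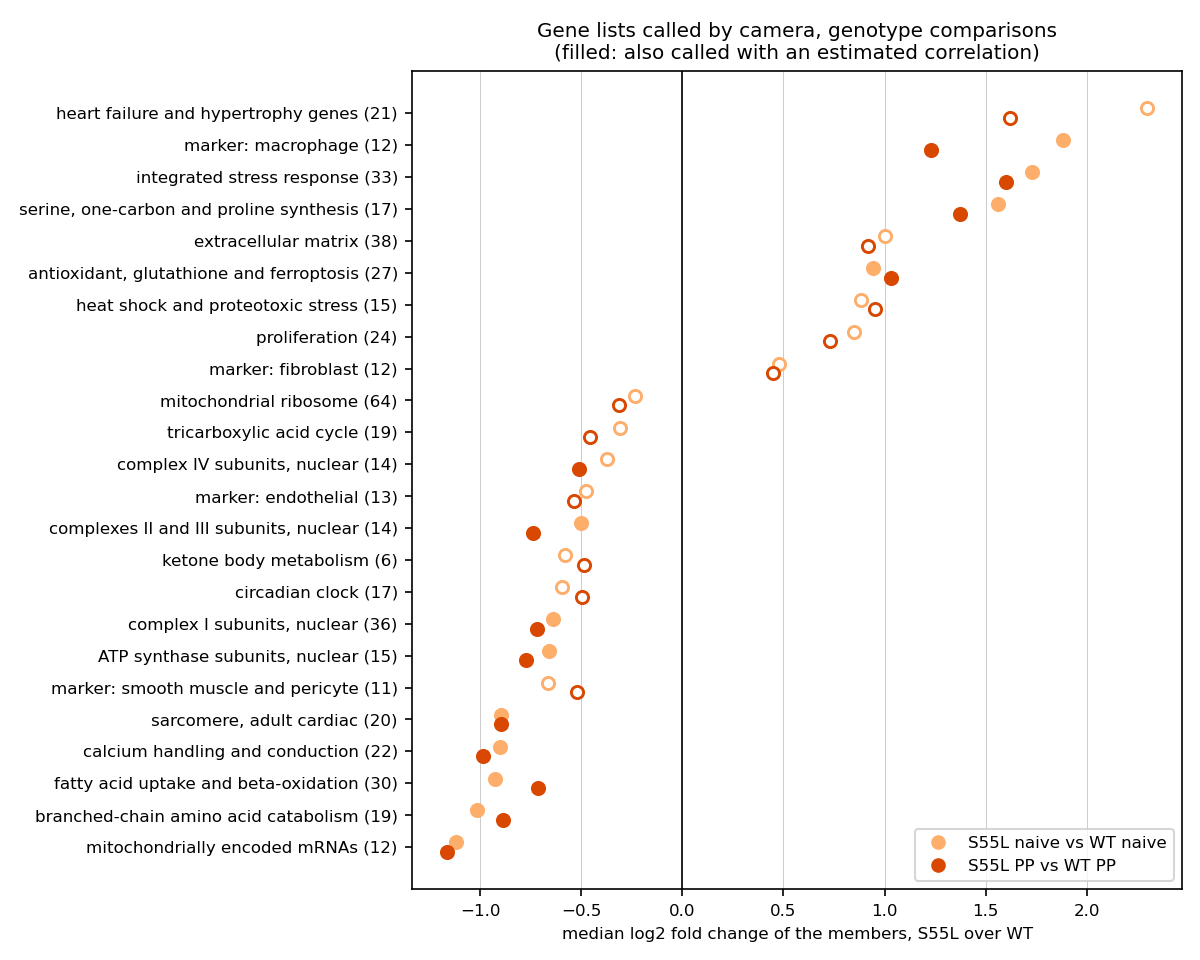
Median log2 fold change of S55L over WT for the gene lists called by camera in naive or PP mice, with the number of measured members in brackets, filled where the call held with an estimated correlation. Stress and matrix lists lie right of 0 and mitochondrial, metabolic and contractile lists left of 0 in both comparisons, except that with total counts as the scaling the naive mitochondrial ribosome median moves to 0.01.

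The S55L PP against WT PP comparison asks what the mutation does in the heart just after pregnancy. Mthfd2 again stood out, at 346 ± 57.3 CPM in S55L PP against 5.34 ± 1.28 in WT PP (SD, n = 4 each; log2 fold change 6.01, SE 0.27, adjusted p = 5.7e-15). Gdf15 was at 237 ± 119.7 against 1.19 ± 1.12 CPM (log2 fold change 7.44, SE 0.56, adjusted p = 1.9e-08), and Atf4 at 255 ± 54.9 against 62.5 ± 25.0 (log2 fold change 2.02, SE 0.20, adjusted p = 1.8e-08). Cox7a1 and Hrc were lower, with log2 fold changes of -2.23 (SE 0.16, adjusted p = 7.9e-11) and -2.42 (SE 0.20, adjusted p = 5.3e-10). The groups did not overlap for any of these 5 genes. The Chchd10 transcript was not called (4170 ± 1298 against 3410 ± 1266 CPM, log2 fold change 0.29, SE 0.21, adjusted p = 0.31), and its interaction with PP was not called either, at -0.44 (adjusted p = 0.997). Without WT PP 5 it was called, at 0.58 (adjusted p = 0.024, 0.0083 to 0.85 over its alternatives).

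The integrated stress response, serine and one-carbon, and antioxidant lists were higher here as well, and heat shock only with the preset correlation. In the integrated stress response 26 of 33 measured members rose and 1 fell (27 and 1 adjusted over the list alone). Its median log2 fold change was 1.60, with camera adjusted p = 7.9e-17 and adjusted p = 0.0048 with an estimated correlation. The median was the same with its member without WT counts at its bound. The asparagine synthetase gene Asns was at 5.28 (SE 0.37), Chac1 at 3.96 (SE 0.27), Trib3 at 4.31 (SE 0.37) and Ddit3 at 1.58 (SE 0.24). Fgf21 had no counts in WT PP and 3.68 ± 1.89 CPM in S55L PP, at least 11.2-fold higher. In serine, one-carbon and proline synthesis 9 of 17 measured members rose (10 adjusted over the list alone). The list median was 1.37, with camera adjusted p = 2.3e-07 and adjusted p = 0.0030 with an estimated correlation. Psat1 was at 4.88 (SE 0.40) and Aldh18a1 at 2.98 (SE 0.28). Phgdh, with 3 counts in WT PP, was 49.7-fold (95% counting interval 16.8 to 243) higher. In the antioxidant list 16 of 27 measured members rose and 1 fell (17 and 2 adjusted over the list alone). The list median was 1.03, with camera adjusted p = 8.4e-09 and adjusted p = 0.0083 with an estimated correlation. Srxn1 was at 3.90 (SE 0.23) and the quinone reductase Nqo1 at 2.96 (SE 0.20), while Gpx4 was at 0.12 (SE 0.58, adjusted p = 0.90). In the heat shock list 8 of 15 measured members rose (10 adjusted over the list alone, median 0.95, camera adjusted p = 2.2e-05, adjusted p = 0.070 with an estimated correlation), with Sqstm1 at 2.82 and Hsp90aa1 at 2.06. Lonp1 was at 1.80 (SE 0.16), in a list of mitochondrial chaperones and proteases that did not pass (camera adjusted p = 0.16). In the heart failure list 15 of 21 measured members rose and 1 fell (16 and 1 adjusted over the list alone, median 1.62, camera adjusted p = 8.4e-09, adjusted p = 0.070 with an estimated correlation). Nppa was at 4052 ± 1078 against 425 ± 284 CPM (log2 fold change 3.25, SE 0.61, adjusted p = 0.00084), Myh7 at 3.66 (SE 0.46) and Myh6 at -0.98 (SE 0.18). Nppb (0.37, SE 0.74, adjusted p = 0.74) and Acta1 (0.90, SE 0.38, adjusted p = 0.085) were not called, and their differences from the naive comparison were not called either (interaction -2.04 and -1.40, adjusted p = 0.997 for both). Both rest on single libraries: without WT PP 5 Nppb was at 2.18 (adjusted p = 0.0051, 0.0017 to 0.98 over its alternatives; interaction -0.23) and Acta1 at 1.29 (adjusted p = 0.016), and without S55L PP 4 Acta1 was at 1.10 (adjusted p = 0.038, 0.0019 to 0.30 over its alternatives). In the extracellular matrix list 27 of 38 measured members rose and 1 fell (28 and 1 adjusted over the list alone, median 0.92, camera adjusted p = 2.1e-11, adjusted p = 0.074 with an estimated correlation), with Col5a2 at 1.78 and the growth factor Tgfb2 at 3.102. Of the fibroblast markers 5 of 12 rose (median 0.45, camera adjusted p = 0.0076, adjusted p = 0.097 with an estimated correlation). Macrophage markers were higher, as 9 of 12 measured members rose (9 adjusted over the list alone). The list median was 1.23, with camera adjusted p = 1.9e-07 and adjusted p = 0.0057 with an estimated correlation. C1qc was at 1.80 (SE 0.18) and the chemokine receptor Cx3cr1 at 3.20 (SE 0.33).

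Oxidative phosphorylation, fatty acid, branched-chain amino acid, calcium handling and adult sarcomere lists were lower in S55L PP by camera. In complex I 27 of 36 measured members fell (31 adjusted over the list alone). Its median log2 fold change was -0.72, with camera adjusted p = 1.1e-12 and adjusted p = 0.0048 with an estimated correlation. Ndufb10, Ndufv2 and Ndufs4 were at -1.03, -1.003 and -0.80. In complexes II and III 12 of 14 measured members fell (13 adjusted over the list alone). The list median was -0.74, with camera adjusted p = 1.9e-07 and adjusted p = 0.013 with an estimated correlation. Uqcrq was at -0.89. In complex IV 2 of 14 measured members rose and 11 fell (2 and 11 adjusted over the list alone). The list median was -0.51, with camera adjusted p = 0.00070 and adjusted p = 0.040 with an estimated correlation. Cox8b was at -1.65 and Cox4i1 at -1.17. In ATP synthase 12 of 15 measured members fell (13 adjusted over the list alone). The list median was -0.77, with camera adjusted p = 1.9e-07 and adjusted p = 0.0019 with an estimated correlation. Of the mitochondrially encoded mRNAs 11 of 12 measured members fell (12 adjusted over the list alone). The list median was -1.16, with camera adjusted p = 8.6e-09 and adjusted p = 0.029 with an estimated correlation. Such genes took 12.3% ± 3.06 of the reads on genes in S55L PP against 20.9% ± 3.55 in WT PP (SD, n = 4 each). In the mitochondrial ribosome 2 rose and 18 fell of 64 (median -0.32, camera adjusted p = 4e-05, adjusted p = 0.096 with an estimated correlation). In fatty acid uptake and beta-oxidation 3 of 30 measured members rose and 23 fell (3 and 24 adjusted over the list alone). The list median was -0.71, with camera adjusted p = 2.3e-08 and adjusted p = 0.013 with an estimated correlation. Acsl1, Acaa2 and the lipoprotein lipase gene Lpl were at -1.32, -1.43 and -1.28. In branched-chain amino acid catabolism 1 of 19 measured members rose and 13 fell (1 and 14 adjusted over the list alone). Its median log2 fold change was -0.89, with camera adjusted p = 3.7e-08 and adjusted p = 0.0057 with an estimated correlation. Ivd was at -1.71 and Ppm1k at -1.92. The tricarboxylic acid cycle (11 of 19 fell) and ketone body (3 of 6 fell) lists had camera adjusted p = 8.4e-05 and 0.028, and adjusted p = 0.093 and 0.097 with an estimated correlation. The ketone body list did not pass without WT PP 5 (adjusted p = 0.12, 0.0060 to 0.14 over its alternatives). In calcium handling 13 of 22 measured members fell (15 adjusted over the list alone). The list median was -0.99, with camera adjusted p = 1.9e-07 and adjusted p = 0.0067 with an estimated correlation. The pacemaker channel Hcn4 was at -3.68 (SE 0.40). In the adult sarcomere 13 of 20 measured members fell (15 adjusted over the list alone). The list median was -0.90, with camera adjusted p = 2.3e-08 and adjusted p = 0.015 with an estimated correlation. Cmya5 was at -2.02 and Tnni3 at -1.74. Nmrk2 was higher, at 290.3 ± 146 against 26.0 ± 31.6 CPM (log2 fold change 3.42, SE 0.61, adjusted p = 0.00057). Nampt was lower (-0.68, SE 0.20, adjusted p = 0.0087), a call lost without WT PP 1 (-0.47, adjusted p = 0.078) and with total counts as the scaling (-0.41, adjusted p = 0.14), 0.00073 to 0.14 over its alternatives. Circadian clock genes were lower (5 of 17 fell, with Hlf at -2.73), as were endothelial (4 of 13) and smooth muscle markers (5 of 11, and 1 rose). These 3 lists had camera adjusted p = 0.016, 0.0018 and 0.030, and adjusted p = 0.16, 0.088 and 0.19 with an estimated correlation. The smooth muscle call was lost without any of WT PP 1, WT PP 5, S55L PP 3 or S55L PP 5 (adjusted p = 0.057, 0.063, 0.051 and 0.073, 0.0063 to 0.19 over its alternatives). In the proliferation list 9 of 24 measured members rose and 1 fell (13 and 2 adjusted over the list alone, median 0.73, camera adjusted p = 0.010, adjusted p = 0.38 with an estimated correlation), and the list did not pass without WT PP 5 (adjusted p = 0.061, 1.9e-05 to 0.38 over its alternatives).

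The edgeR test called 3767 of 11945 genes between S55L PP and WT PP, of which 1816 were down and the rest up. At least 2-fold, 961 were up and 847 down. In 2677 of them the 4 libraries of each genotype did not overlap, and over all genes this share was 25.4% where chance gives 2.86%. The largest rises were in genes without or nearly without WT PP counts: Vmn2r3 was at least 101-fold, the cationic amino acid transporter Slc7a3 at least 51.9-fold and Cyb5r2 at least 39.5-fold higher, the glutathione transferase Gsta2, which has close paralogues, 315.8-fold (95% counting interval 87.2 to 2611) and Krt18 215-fold (95% counting interval 38.3 to 8505). The largest falls were in Lingo3 (-4.79), Pfkfb1 (-4.36), Myot (-4.27), the carboxylesterase Ces1d (-4.12), Shank3 (-4.02) and the receptor Gpr22 (-3.81). Of the called genes named above, only Nampt had overlapping groups. Pdk4 (0.71, SE 0.33, adjusted p = 0.11) and Tfrc (-1.13, SE 0.43, adjusted p = 0.056) were not called, but without WT PP 1 Tfrc was at -1.49 (adjusted p = 1.4e-06, 1.4e-06 to 0.17 over its alternatives). With the plate column as a term, which leaves S55L PP 5 against WT PP 1 alone, Tfrc was at 1.35. By camera 9 of 42 lists were higher and 15 lower, and 4 and 9 of these kept their call with an estimated correlation. The lists of iron handling and heme, the cytosolic ribosome, the interferon response, glucocorticoid-responsive genes, prolactin and STAT5-responsive genes, cholesterol synthesis, lipogenesis and immediate early genes did not pass (camera adjusted p = 0.055 to 0.99), although iron handling and heme did without WT PP 1 or S55L PP 5 (adjusted p = 0.019 and 0.028, 0.011 to 0.96 over its alternatives). Scaling by total counts moved the median of all genes by 0.27 and gave 3458 up and 977 down. With the plate column as a term 2108 genes were called (1070 up and 1038 down), 1636 of them among the 3767, and in 1675 of the 2131 calls that ended the SE grew by a larger factor than the fold change shrank. Nppa went from 3.25 (SE 0.61) to 3.23 (SE 1.32), Shank3 from -4.02 (SE 0.58) to -4.04 (SE 1.36), Nampt from -0.68 (SE 0.20) to -0.85 (SE 0.34) and Myh6 from -0.98 (SE 0.18) to -0.82 (SE 0.34), while Ndufs4 shrank as well, from -0.80 (SE 0.13) to -0.46 (SE 0.25). Of the lists that lost their call with the term, ketone bodies kept their median (-0.53 against -0.49), and it moved toward 0 for complex IV (-0.28 against -0.51), the mitochondrial ribosome (-0.01 against -0.32) and the tricarboxylic acid cycle (-0.24 against -0.46). The adjusted p with the term was 0.11 for Nppa (2e-08 to 0.11 over its alternatives), 0.094 for Myh6 (1.6e-07 to 0.094) and 0.052 for Shank3 (3.9e-19 to 0.052).

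The genotype differences of naive and PP mice overlapped, and 0 genes were called in the interaction of genotype and PP. Of the genes tested, 1672 rose in both naive and PP mice, where 427 would if the calls were independent, and 1543 fell in both, where 392 would. No gene was called in opposite directions, and the log2 fold changes correlated across genes at r = 0.90, although genes are not independent replicates. The 2 comparisons share no library, but the plate column runs with genotype in both. With the plate column as a term 1650 genes changed alike in both, 807 of them up and the rest down, and with total counts as the scaling 2937 rose and 839 fell.

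The WT PP against WT naive comparison asks how the normal heart differs just after pregnancy. Ucp3 (ENSMUSG00000032942), a mitochondrial carrier induced by fatty acids, fell from 56.7 ± 13.4 to 12.7 ± 2.28 CPM (SD, n = 5 naive and 4 PP; log2 fold change -2.14, SE 0.23, adjusted p = 7e-06). Lgals4 (ENSMUSG00000053964), a galectin, fell from 90.0 ± 12.0 to 39.8 ± 6.45 CPM (log2 fold change -1.19, SE 0.16, adjusted p = 0.00048), a call lost without the 5 libraries of outer plate rows (-0.92, adjusted p = 0.070, 1e-08 to 0.070 over its alternatives). All 4 PP libraries lay below all 5 naive libraries for both genes. They were the only genes of 11945 called by edgeR, with 756 at an unadjusted p under 0.05, 12 called by DESeq2, 2 by limma voom, and 10 by edgeR without WT PP 1. Over all genes 1.88% had groups without overlap, where chance gives 1.59%. Pdk4, which restrains glucose oxidation, had 61.0 ± 20.03 CPM in PP against 169 ± 79.9 and no overlap, but was not called (-1.46, SE 0.32, adjusted p = 0.25). The transferrin receptor gene Tfrc had 159 ± 90.0 CPM in PP against 30.3 ± 8.91 and was not called either (2.38, SE 0.44, adjusted p = 0.22), but without WT PP 1 it was at 2.75 and called (adjusted p = 6.6e-10, 6.6e-10 to 0.67 over its alternatives). Nppb (2.07, SE 0.74, adjusted p = 0.67), Nmrk2 (1.95, SE 0.72, adjusted p = 0.67) and Mthfd2 (1.05, SE 0.40, adjusted p = 0.67) were not called, and the first 2 of these values come from WT PP 5. That library had 906.9 CPM of Nppb and 72.8 of Nmrk2, where the other WT PP libraries had 55.6 to 121 and 6.17 to 17.9, and without it they were at 0.26 and 0.53. Macrophage markers were higher as a group, with 0 of 12 members called over all genes and 4 adjusted over the list alone (median log2 fold change 0.62, camera adjusted p = 9.4e-07 and adjusted p = 0.034 with an estimated correlation). Fatty acid uptake and beta-oxidation, which holds Ucp3, was lower (median log2 fold change -0.17, camera adjusted p = 9.4e-07 and adjusted p = 0.098 with an estimated correlation), and 1 of its 30 members was called over all genes (2 adjusted over the list alone). Heart failure genes were higher (median 0.45, camera adjusted p = 1.2e-05 and adjusted p = 0.48 with an estimated correlation). So were extracellular matrix genes (median 0.29, camera adjusted p = 3.5e-05 and adjusted p = 0.53 with an estimated correlation). The heart failure call was lost without WT PP 5 (median 0.12, adjusted p = 0.21, 1.7e-07 to 0.48 over its alternatives). Proliferation genes were higher (median log2 fold change 0.69, camera adjusted p = 4e-05 and adjusted p = 0.48 with an estimated correlation), and with only the compared groups in the fit they did not pass (median 0.02, adjusted p = 0.49, 2.3e-09 to 0.49 over its alternatives). The remaining camera calls were the mitochondrial ribosome (0.08), prolactin and STAT5-responsive genes (0.44), serine and one-carbon synthesis (0.36), heat shock (0.19), the cytosolic ribosome (0.09), the circadian clock (-0.23) and erythroid markers (-0.22). Their adjusted p ran from 0.016 to 0.043, and from 0.43 to 0.66 with an estimated correlation. All of them except the erythroid call were lost without WT PP 5 alone, the erythroid call without WT naive 2, WT naive 3 or WT PP 1, and no library of these 2 groups could be left out without the loss of at least 1 of these 7 calls. Without WT PP 1 the erythroid median was -0.08 (adjusted p = 0.90, 0.00079 to 0.90 over its alternatives). The prolactin list had a median of 0.05 without WT PP 5.

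**Figure D3:**
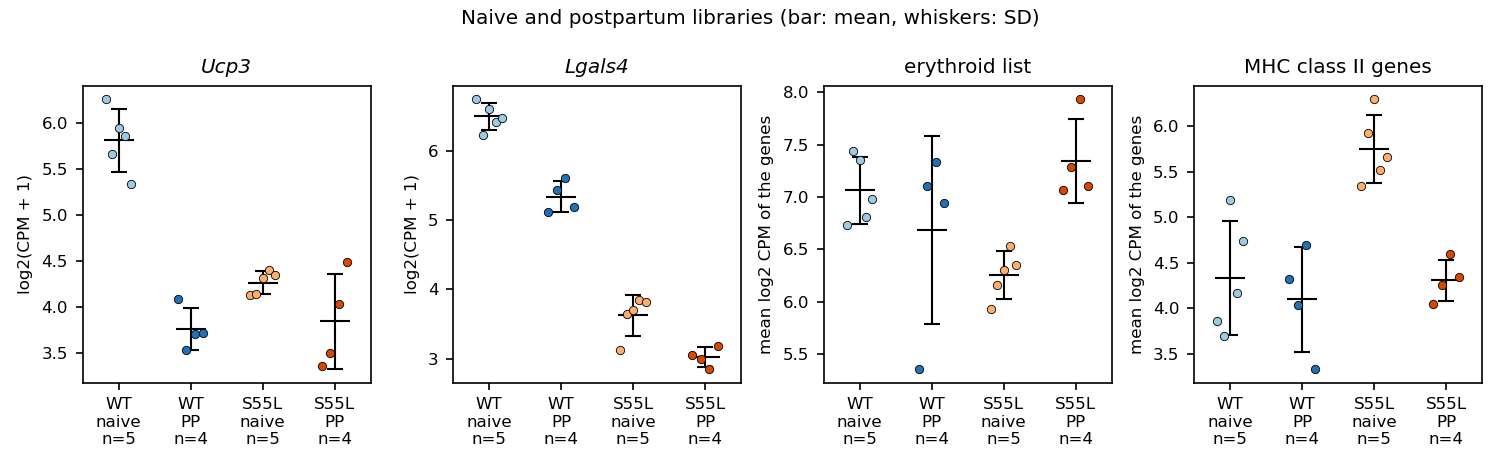
Ucp3 and Lgals4 (log2 of CPM plus 1) and the mean log2 CPM of 7 erythroid and 5 MHC class II genes in each library, by group, with the group mean as a bar and the SD as whiskers. Ucp3 and Lgals4 are lower in every WT PP library than in any WT naive library, erythroid means are 7.06 to 7.93 in S55L PP against 5.93 to 6.54 in S55L naive, and MHC class II means are 4.04 to 4.59 against 5.34 to 6.29.

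The S55L PP against S55L naive comparison asks the same of the mutant heart. No gene was called by edgeR (0 of 11945, lowest adjusted p = 0.069, 747 at an unadjusted p under 0.05), while DESeq2 called 18 and limma voom 20, and edgeR called 2 without S55L naive 1 or without S55L naive 4 and 1 without S55L naive 5 or without S55L PP 4. Cd74 was among these without S55L naive 1, 4 or 5 (-1.91, -1.90 and -1.93), and Mmp3 without S55L naive 1 or S55L PP 4 (2.02 and 1.90). The lowest adjusted p belonged to genes chosen after their values were seen: Cd74, the invariant chain of MHC class II, at -1.80 (SE 0.32, adjusted p = 0.069), H2-Eb1, an MHC class II chain, at -1.42 (SE 0.26, adjusted p = 0.069), and the acute-phase serpin Serpina3n at 1.48 (SE 0.28, adjusted p = 0.069). H2-Ab1 (-1.77, SE 0.36, adjusted p = 0.16), the matrix protease Mmp3 (1.64, SE 0.34, adjusted p = 0.11) and Alas2, the erythroid enzyme of heme synthesis (1.48, SE 0.33, adjusted p = 0.16), had higher adjusted p. Ucp3 and Lgals4, which fell in WT PP, were not called here (-0.39, SE 0.21, adjusted p = 0.81 and -0.69, SE 0.20, adjusted p = 0.53). Gdf15 was at 237 ± 119.7 CPM in PP against 190.1 ± 53.0 naive (0.32, SE 0.32, adjusted p = 0.91), Mthfd2 at 0.08 (SE 0.18, adjusted p = 0.96), Nppa at 0.81 (SE 0.53, adjusted p = 0.85) and Nmrk2 at 0.33 (SE 0.50, adjusted p = 0.95). Over all genes 2.25% had groups without overlap, where chance gives 1.59%. As lists, by camera, extracellular matrix genes were higher (median log2 fold change 0.27, camera adjusted p = 7.8e-10 and adjusted p = 0.49 with an estimated correlation), with 6 members called adjusted over the list alone. Erythroid markers were higher (median log2 fold change 1.46, camera adjusted p = 1.4e-09 and adjusted p = 0.20 with an estimated correlation), with 5 of 7 adjusted over the list alone and a median of 0.476 with the plate column as a term. Proliferation (median log2 fold change 0.45, camera adjusted p = 9.5e-09 and adjusted p = 0.38 with an estimated correlation) and heart failure genes (median log2 fold change 0.37, camera adjusted p = 1.4e-06 and adjusted p = 0.49 with an estimated correlation) were higher, the latter with 3 members adjusted over the list alone, and with the plate column as a term the heart failure call was lost (median 0.13, adjusted p = 0.15, 1.9e-09 to 0.49 over its alternatives). Glucocorticoid-responsive genes were lower (median log2 fold change -0.36, camera adjusted p = 0.012 and adjusted p = 0.66 with an estimated correlation), a call lost without S55L naive 1 (median -0.17, adjusted p = 0.23), S55L naive 4 (0.063), S55L PP 1 (0.052) or S55L PP 4 (0.24), with 3.4e-05 to 0.82 over its alternatives.

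The interaction of genotype and PP asks whether pregnancy changes the mutant heart differently from the normal heart. No gene was called by edgeR (0 of 11945, lowest adjusted p = 0.074, 444 at an unadjusted p under 0.05), DESeq2 called 1 and limma voom 0. Without WT PP 1 edgeR called 2 genes, and without WT naive 5, S55L PP 1 or S55L PP 3 it called 1, with Ucp3 among them each time (1.89, 1.86, 1.90 and 1.88). The lowest adjusted p was that of Ucp3 (1.75, SE 0.31, adjusted p = 0.074), chosen after its value was seen, and Lgals4 was at 0.50 (SE 0.26, adjusted p = 0.997). Without WT PP 1 Tfrc was called as well, at -2.43 (adjusted p = 8.6e-06, 8.6e-06 to 0.999976 over its alternatives). Of the genes named in every comparison, Tfrc was at -2.07 (SE 0.60, adjusted p = 0.997), Acta1 at -1.40 (SE 0.51, adjusted p = 0.997), Nppb at -2.04 (SE 1.02, adjusted p = 0.997), Pdk4 at 1.05 (SE 0.43, adjusted p = 0.997) and Mthfd2 at -0.97 (SE 0.44, adjusted p = 0.997). In all, 3 lists passed by camera. The PP change of erythroid markers was higher in S55L than in WT (median log2 fold change 1.62, camera adjusted p = 3.9e-10 and adjusted p = 0.15 with an estimated correlation). That of macrophage markers was lower (median -0.46, camera adjusted p = 0.0022 and adjusted p = 0.20 with an estimated correlation). That of fatty acid uptake and beta-oxidation was higher (median 0.13, camera adjusted p = 0.0081 and adjusted p = 0.56 with an estimated correlation). The fatty acid call was lost without WT naive 1 (median 0.09, adjusted p = 0.11, 0.00038 to 0.56 over its alternatives), with the plate column as a term (0.07) and without the 5 outer-row libraries (0.0043), and with the plate column as a term the macrophage median was -0.21 (adjusted p = 0.58, 4.8e-06 to 0.58 over its alternatives).

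The EH301 against control diet comparison asks whether the supplement changes the mutant heart at postpartum day 0. No difference between the diets was detected in any single gene. Gdf15 was at 994 ± 591.8 CPM on EH301 against 1068 ± 745 on the control diet (SD, n = 4 each; log2 fold change -0.10, SE 0.49), Mthfd2 at 335 ± 87.9 against 371 ± 163 (-0.14, SE 0.34) and Atf4 at 1244 ± 726 against 1312 ± 1033 (-0.07, SE 0.51). These values rest on single libraries: without control diet 1, the shallowest, Gdf15 was at 0.50, Mthfd2 at 0.18 and Atf4 at 0.63, and without EH301 diet 8 at -0.61, -0.28 and -0.58, none of them called. Nmrk2, whose enzyme phosphorylates nicotinamide riboside, was at 139 ± 23.4 against 191 ± 31.2 CPM (-0.46, SE 0.24) and Nampt at 0.08 (SE 0.25). Nppa was at -0.04 (SE 0.35), Myh7 at -0.25 (SE 0.46), Acta1 at 0.30 (SE 0.25) and Chchd10 at 0.16 (SE 0.38). All of these had an adjusted p of 0.9999, the lowest of the comparison. Of 10335 genes edgeR called 0, with 137 at an unadjusted p under 0.05, DESeq2 called 0 and limma voom 1. Groups did not overlap in 155 genes, where chance gives 2.86% of 10335. In the simulated data 8.96% of genes changed 2-fold and 86.4% changed 4-fold were recovered. Such 2-fold changes were thus mostly not detectable at this depth and number of libraries. By camera genes of the unfolded protein response of the endoplasmic reticulum were higher on EH301 (median log2 fold change 0.22, camera adjusted p = 0.0047 and adjusted p = 0.91 with an estimated correlation) and erythroid markers lower (median log2 fold change -0.76, camera adjusted p = 0.033 and adjusted p = 0.91 with an estimated correlation), with 0 members of either called. The unfolded protein response call was lost without control diet 1 (adjusted p = 0.18, 0.0018 to 0.91 over its alternatives). The erythroid call was lost without control diet 2 (adjusted p = 0.084), control diet 3 (0.57), EH301 diet 9 (0.078) or EH301 diet 10 (0.42), with 1.3e-06 to 0.91 over its alternatives. The integrated stress response list had a median of 0.19 (camera adjusted p = 0.11), and the heart failure list -0.06 (camera adjusted p = 0.058). The first passed as higher without control diet 1, EH301 diet 7 or EH301 diet 10 (adjusted p = 0.0097, 0.017 and 0.015, 0.0097 to 0.91 over its alternatives) and the second as lower without control diet 4, EH301 diet 7 or EH301 diet 10 (adjusted p = 0.032, 0.017 and 0.028, 0.0066 to 0.91 over its alternatives). A score for the genotype signature took the 3135 measured genes called between S55L PP and WT PP, signed by their change there. Its mean difference, EH301 minus control diet, was 0.0487 log2 units toward the mutant direction (exact permutation test of the 70 assignments, 2-sided, p = 0.314, smallest possible 0.0286, n = 4 against 4). That value was 0.0259 without EH301 diet 8, 0.0310 without control diet 1, 0.0773 without EH301 diet 10 and 0.0799 without control diet 3, and 0.0062 without the 2 libraries under 1200000 reads.

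**Figure D4:**
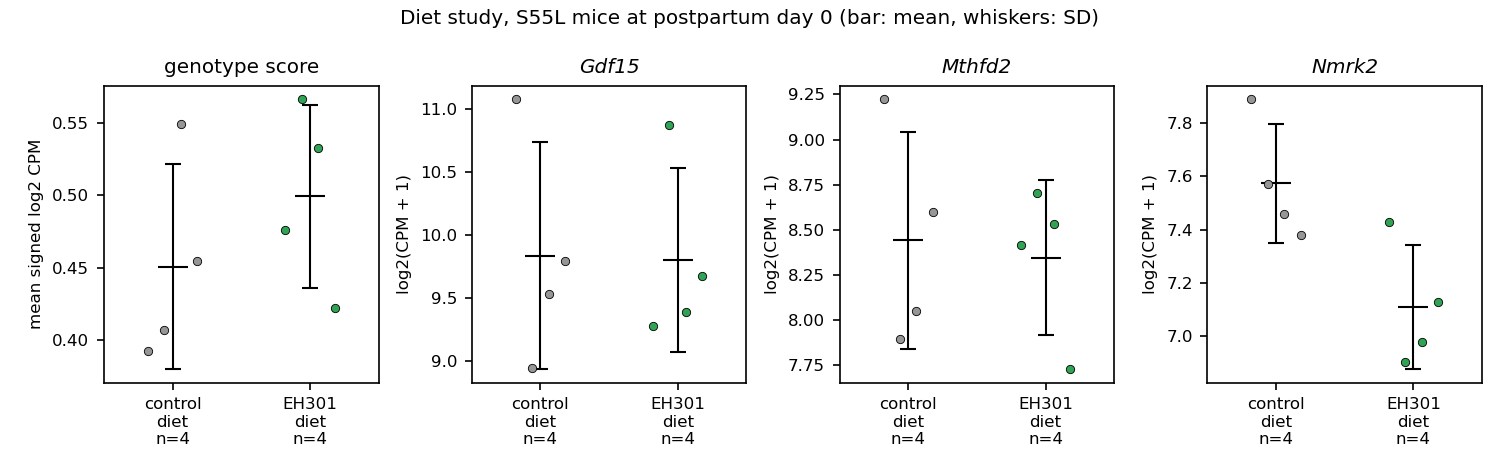
Genotype score (mean signed log2 CPM of 3135 genes) and Gdf15, Mthfd2 and Nmrk2 (log2 of CPM plus 1) in each library of the diet study, by diet, with the mean as a bar and the SD as whiskers (n = 4 each). The scores of the diets overlap, at 0.392 to 0.550 on the control diet and 0.422 to 0.567 on EH301.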

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

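Of the fits in this part, the plate term, removal of mitochondrially encoded genes and leaving out each library were fixed beforehand. Their use as tests, the other tests and the counts over other splits were chosen after the results were seen. The difference between S55L and WT hearts was weighed against the plate column, library depth and mitochondrially encoded reads. With every library thinned to 1418715 reads, 75.1% of the naive and 71.9% of the PP calls were kept, which argues against depth as the whole cause. With mitochondrially encoded genes removed 99.4% and 99.3% were kept. That removal moved the naive median of all genes only from -0.0039 to -0.0044, so it cannot decide on these reads. On a scale over the 5192 genes with WT naive at 0 and S55L naive at 1, WT PP 1, the only WT library in a plate column with S55L libraries, lay at 0.0266, the other WT PP libraries at 0.101 to 0.240 and S55L PP libraries at 0.840 to 1.06. A plate effect as the whole cause would put WT PP 1 nearer to 1, but this is 1 library, so the plate column stays open as a part of the cause. A lost call with the plate term is no evidence for it where the change kept its size: over the 5192 genes the log2 fold change with the term was 1.21 times its size at the median, and over the 2695 lost calls 0.919 times, while their median SE went from 0.220 to 0.444.

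Erythroid transcripts were higher in S55L PP than in S55L naive as a list by camera (median log2 fold change 1.46, 7 genes, adjusted p = 1.4e-09, but adjusted p = 0.20 with an estimated correlation), with 0 genes called by edgeR over all genes (747 at an unadjusted p under 0.05, DESeq2 18 and voom 20). Their mean lay at 7.06 to 7.93 log2 CPM in S55L PP, 5.93 to 6.54 in S55L naive, 5.36 to 7.33 in WT PP and 6.73 to 7.44 in WT naive. Without the outer-row libraries the median was 1.78, and without each library in turn it was 1.03 to 1.64, which argues against the plate row or a single library as the cause. With a plate column term it was 0.476, so the plate column may account for part of it, although 1 S55L PP library alone shares a column with the naive ones. A PP state shared by both genotypes would raise the WT level too, but the WT PP mean differed from WT naive by -0.380 (SE 0.472), and by 0.0629 (SE 0.183) without WT PP 1, where the S55L means differed by 1.09 (SE 0.225), which argues against it. The plate column and a PP effect in the mutant alone stay open, the latter untested, and how much blood each heart held is not given.

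The MHC class II genes had a median log2 fold change of -1.72 in S55L PP against S55L naive (5 genes, at 4.04 to 4.59 against 5.34 to 6.29 in mean log2 CPM per library), but edgeR called none of them (adjusted p = 0.069 to 0.80), and they were picked after their values were seen, so the fall itself is not established. Fewer macrophages would lower the macrophage markers as well, but their median was 0.115, and without the outer-row libraries the MHC class II median was -1.32, which argues against both. With a plate column term it was -1.76, which rests on 1 S55L PP library, so the plate column and the postpartum state cannot be told apart. No other biological explanation was tested.

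Other splits of the same libraries show where chance can be excluded as the source of a count of called genes. Between the naive genotypes it can: 1 of 100 splits drawn, the real one, called as many as 5192 genes, and the highest other called 81. Between the PP genotypes it can: 1 of 35 splits called as many as 3767, and the highest other, which exchanges 1 library between the genotypes, called 914. For WT PP against WT naive 3 of 100 splits called as many as 2. Those beside the real one kept WT PP 3, 4 and 5, so this cannot decide on chance. Where 0 genes were called the splits say nothing about chance, since each split calls at least 0: 100 of 100 for S55L PP against S55L naive (highest other 20), 100 of 100 for the interaction (18) and 35 of 35 for the diets (450). The split of the diet libraries with 450 genes, which sets control diet 1 and 4 with EH301 diet 8 and 10 against the rest, points to a structure of these samples other than diet. Its first side had 6.95% to 18.9% of reads on mitochondrially encoded genes and held both libraries under 1200000 reads, and the rest had 21.7% to 24.65%.

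Of 134 groups of values examined, 9 held a library far from the others of its group, where chance gives about 1 in 20, or 6.7. Reads on genes made up 61.5% in WT naive 5 (others 58.3% to 59.2%) and 61.6% in WT PP 5 (59.0% to 59.4%). On the log2 CPM scale, Mthfd2 was at -0.63 in WT naive 1 (others 1.84 to 2.22), Gdf15 at 1.81 in WT PP 5 (0.27 to 0.46) and Tfrc at 4.68 in WT PP 1 (7.61 to 7.77). Myh6 was at 12.77 in S55L PP 1 (13.02 to 13.04) and Pdk4 at 6.07 in the same library (6.77 to 6.91). Chchd10 was at 10.87 in control diet 1 (12.11 to 12.19), and Atf4 at 11.19 in EH301 diet 8 (9.70 to 9.83). The PP change of 3 lists differed between the genotypes by camera on the interaction: erythroid markers at 1.62 (adjusted p = 3.9e-10, adjusted p = 0.15 with an estimated correlation), macrophage markers at -0.46 (adjusted p = 0.0022 and 0.20) and fatty acid uptake and beta-oxidation at 0.13 (adjusted p = 0.0081 and 0.56).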

How the results depend on the processing

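Of these alternatives, the ones that use all deposited columns, thinned counts, outer plate rows, the library under both diets or shallow libraries were chosen after the data were seen. Genes that rose in both genotype comparisons (1672) were 2937 with total counts and 807 with the plate column as a term, and genes that fell in both (1543) were 839 with total counts and about 8.4e+02 with the plate term, which left 1650 that changed alike in both. The plate term took the calls between the naive genotypes from 5192 to 2873 and between the PP genotypes from 3767 to 2108. Between the PP genotypes that term leaves S55L PP 5 against WT PP 1 alone. Leaving out 1 library gave 4564 to 4967 and 3086 to 4146 calls, and every other alternative stayed within 1.5 times of 5192 and of 3767. The 2 calls of WT PP against WT naive became 21 without a filter, 12 with DESeq2, 21 with the plate term and 6 without the 5 outer-row libraries, and 2 to 10 without each library, with 10 without WT PP 1. The 0 calls of S55L PP against S55L naive (edgeR, 747 at an unadjusted p under 0.05) became 3 with total counts, 37 without a filter, 18 with DESeq2, 20 with voom, 1 with the plate term, 3 with only the compared groups, 10 with all deposited columns, 2 with an outer-row term, 8 without outer-row libraries and 2 thinned, and 0 to 2 without each library. The 0 calls of the interaction (edgeR, 444 at an unadjusted p under 0.05) became 5 without a filter, 1 with DESeq2, 2 with the plate term, 2 with an outer-row term and 2 without outer-row libraries, and 0 to 2 without each library. The 0 calls between the diets (edgeR, 137 at an unadjusted p under 0.05, DESeq2 0) became 1 with voom, which was Pfdn6, chosen after its value was seen, and stayed 0 without each library. The diet score of 0.0487 was 0.0259 to 0.0799 without each library, 0.0062 without the 2 shallowest libraries and 0.0375 with all deposited columns, and its p stayed above 0.05, which without a library could not be otherwise, as the smallest possible p was then 0.0571. With the plate term Hba-a2 between the naive genotypes went from -1.23 to 1.30, Hba-a1 from -1.23 to 0.92 and Tfrc between the PP genotypes from -1.13 to 1.35. The erythroid median of WT PP against WT naive, -0.22, was -0.0793 with the plate term, 0.0076 without outer-row libraries and -0.35 to -0.0762 without each library, where the camera direction turned without WT PP 1. The glucocorticoid median of S55L PP against S55L naive, -0.36, was -0.0817 with the plate term, where its camera direction turned. For Tfrc the term sets S55L PP 5 (63.9 CPM) against WT PP 1 (25.0). The other WT PP libraries had 194 to 218, so that turn came from WT PP 1. Between the naive genotypes the term takes the column effect from WT PP 1 against the other WT PP libraries. WT PP 1 had the lowest erythroid mean of these, 5.36 log2 CPM against 6.94 to 7.33, so the Hba-a1 and Hba-a2 turns rest on it too. The cause of the other shifts was not tested. Over all alternatives, values of named genes kept their side of the threshold 9422 times, lost a call 169 times and gained one 101 times. They turned direction with a call in either fit 3 times, and for lists these numbers were 5446, 152, 107 and 4. A turn of direction without a call in either fit was counted as kept. With the replicate number as a block 5475, 4122, 2, 0 and 0 genes were called in the 5 comparisons of the postpartum study. Between the PP genotypes it changed the call of 1 named gene, Mbp, from 1.30 (edgeR adjusted p = 0.044) to 1.25 (adjusted p = 0.059). There numbers 1 and 5 also share a row. In the other pairs of groups same-numbered libraries correlated at -0.165 to 0.356, and 10 of 18 libraries correlated best with a library of their own number. The plate term in the diet study was not run, since with the duplicate out the model could not be fitted. The smallest library of the diet study held 466651 reads on genes, and without the 2 shallowest libraries 0 genes were called by edgeR there, with 456 at an unadjusted p under 0.05.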

Other observations

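The gene pairs and the MHC class II genes of this part, and the test of the PP changes, were chosen after values had been seen. In 11 pairs of related genes, each with 1 form that is high in the adult heart and 1 partner, the mean log2 ratio of partner to heart form was higher in S55L naive than in WT naive (n = 5 each). The pairs were picked for this pattern, so the values describe it and no test is given. The ribosomal pair Rpl3 to Rpl3l changed by 5.06, the myosin pair Myh7 to Myh6 by 4.42, and the cytochrome c oxidase pairs Cox8a to Cox8b by 3.24, Cox6a1 to Cox6a2 by 2.95 and Cox7a2 to Cox7a1 by 2.44. The glucose transporter pair Slc2a1 to Slc2a4 changed by 3.08, the hexokinases Hk1 to Hk2 by 2.25, Pgam1 to Pgam2 by 2.47, the adenine nucleotide carriers Slc25a5 to Slc25a4 by 2.28, Ldha to Ldhb by 1.20, and the enolases Eno1 to Eno3 by 1.55. By edgeR 8 of the 11 partners rose, while Cox7a2 (0.03, adjusted p = 0.88), Ldha (0.31, adjusted p = 0.25) and Eno1 (-0.60, adjusted p = 0.16) were not called, so in these 3 pairs the called change was the fall of the heart form. The heart form fell in 10 pairs, and Pgam2 was not called (-0.38, adjusted p = 0.088), but was without S55L naive 3 (-0.58, adjusted p = 0.0071) or WT naive 1 (-0.46, adjusted p = 0.047), with 0.0068 to 0.94 over its alternatives. The plate column as a term ended the calls of Cox6a2 (-1.04, SE 0.22, to -0.66) and Myh6 (-0.57 to -0.41), and total counts that of Myh6 (-0.32). In S55L PP against WT PP (n = 4 each) the changes were Rpl3 to Rpl3l by 4.98, Myh7 to Myh6 by 4.71, Slc2a1 to Slc2a4 by 3.19, Pgam1 to Pgam2 by 2.73, Cox8a to Cox8b by 2.62, Eno1 to Eno3 by 2.40, Cox6a1 to Cox6a2 by 2.28, Cox7a2 to Cox7a1 by 2.10, Hk1 to Hk2 by 2.05, Slc25a5 to Slc25a4 by 1.85 and Ldha to Ldhb by 1.001. The plate term ended the PP calls of Cox6a2 (-0.92 to -1.22), Myh6 (-0.98 to -0.82), Pgam2 (-0.73 to -0.61) and Ldhb (-0.99 to -0.75), and total counts as the scaling that of Pgam2 (-0.44). There too Cox7a2 (-0.17, adjusted p = 0.49), Ldha (-0.0971, adjusted p = 0.79) and Eno1 (0.21, adjusted p = 0.70) were not called. Reads of Rpl3 can be shared with its pseudogenes.

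The MHC class II genes were higher in S55L naive than in WT naive, with Cd74 at 1.03, H2-Aa at 2.01, H2-Ab1 at 1.61, H2-Eb1 at 1.05 and H2-DMa at 1.10 on the log2 scale, all called by edgeR over all genes. The macrophage markers rose in the same comparison (11 of 12, median 1.88), and the 2 rises were not separated. Without the 5 outer-row libraries Cd74 was not called (1.05, adjusted p = 0.064, 6.4e-07 to 0.37 over its alternatives). With the plate column as a term none of the 5 was called: the SE, 0.25 to 0.39 over these genes, became 0.57 to 0.95, while Cd74 (0.94), H2-Aa (2.27) and H2-Ab1 (1.60) kept their size, H2-Eb1 was at 0.70 and H2-DMa at 0.03. The H2-DMa call was also lost without WT naive 1, 2 or 4. Between S55L PP and WT PP they were at -0.63 to 0.60 and none was called.

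A hypothesis is that WT and S55L hearts may share part of their change from naive to PP. The changes of all genes in the 2 genotypes correlated at r = 0.165, and of 10000 permutations of the PP labels within genotype a share of 0.105 reached that value (permutation test, 1-sided, p = 0.105), so the hypothesis stays open.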
